A study of Mus musculus with 20 samples.

How the data were processed

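The samples are livers of C57BL/6 mice on chow (10 libraries) or on the high-fat diet (10 libraries), sequenced from total RNA extracted with Trizol from tissue kept in liquid nitrogen. Groups and replicate numbers were taken from the sample labels. The study's design text speaks of 1 chow group and 3 groups on the high-fat diet, whereas all 10 high-fat diet samples carry the same labels, so they were treated as 1 group. If those 3 groups differed in more than the diet, the high-fat diet means, calls and list tests carry that difference as well. The labels do not state that each sample is a separate mouse, so the p-values measure the spread between these samples. No batch labels are given, and a difference between the diets cannot be separated from a difference in handling or sequencing.

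Per the labels, reads were cleaned with fastp and mapped to mm10 before the authors deposited a table of counts per gene and library. The authors also deposited an FPKM table, in which FPKM equals the count scaled by the library's column total and 1 length per gene for all 27216 genes with counts, within a relative 1e-06. The aligner, the counting program, the annotation and the strandedness are not given in the sources used here. Of 55401 gene IDs 55141 were matched to GENCODE M21, whose coordinates (GRCm38, the same assembly as mm10) are printed, and the 260 unmatched IDs held at most 0.0085% of the counts of a library. Where genes have near-identical copies, how reads were shared between them is unknown, and the values of such genes are uncertain.

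Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total count 15), TMM scaling, a robust quasi-likelihood fit with the diet as the only term, a two-sided quasi-likelihood F test per gene and Benjamini-Hochberg adjustment. A gene is called changed, higher or lower at an adjusted p under 0.05, and larger changes are those of at least 2-fold. CPM values (counts scaled to a library size of 1e+06) use TMM-scaled library sizes, and means, SDs and folds were taken over 10 libraries per diet. Gene lists, fixed before the data were examined, were tested with camera in limma 3.58.1 (inter-gene correlation 0.01, at least 5 tested members, adjusted over 35 lists), again with an estimated correlation, and with fry. Counts "adjusted over the list alone" apply Benjamini-Hochberg to the p-values of the list's members. The list score of a library is the mean log2 CPM (prior count 2) of the members, each centred on the mean of all libraries. Spread within a diet was the Euclidean distance to the group mean over 2000 genes, compared by two-sided permutation of the diet labels (100000 resamples, or exact enumeration where a group had under 10 libraries). Relations between scores used Pearson r and Spearman rho with permutation p-values, adjusted over 10 relations. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

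Named genes follow a rule set before the data were examined. It takes up to 10 genes with the largest log2 change in each direction among called genes with a mean of at least 1 CPM. It also takes up to 4 members per gene list, those with the smallest p-values, a fixed list of liver genes, and Xist and the Y-linked genes. Members picked by p-value are not typical of their list. Symbols of unnamed gene models were passed over, 4 upward and 3 downward. The text prints part of the genes that this rule names, and some of the others are not reported here. Sae1, Igsf23, Relb and Dbp were chosen after their values were seen. The tests, the lists and most alternatives were also chosen before the data were examined; the settings that leave out HFD 1, HFD 2, HFD 6, chow 9 or HFD 6, 8, 9 and 10 together, the setting with nuclear protein-coding genes only and the tests of lists and of named genes without each library were added after seeing the data.

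Alternatives were DESeq2 1.42.0, limma voom with and without sample quality weights, edgeR without robust dispersion, RLE, upper-quartile or no scaling beyond library totals, no filter or a filter of 1 CPM in 10 libraries, limma-trend on log2 FPKM with 1 or 0.1 added, the replicate number as a block, and a refit without each library. Every pair of libraries within a diet was checked for duplication (genes with a combined count of at least 50) and none matched within sampling noise, which gives a chi-square per gene of about 1. The closest pairs were chow 3 with chow 5 (10.6) and HFD 4 with HFD 5 (14.1). The next closest were chow 3 with chow 7 (31.4) and HFD 3 with HFD 5 (32.4). Whether the closest pairs are independent livers was not tested. The gene and list tests were tested on simulated data with the same group sizes, where 67% of 2-fold and 90% of 4-fold changed genes were recovered and 5 of 162 calls were of unchanged genes. The simulation gave each gene 1 mean, apart from the simulated changes, and 1 dispersion for both diets. The mitochondrial share of HFD 1 and HFD 2 and the wider spread in HFD were therefore not simulated. The common biological coefficient of variation was 43.7%. The equal-depth gene count draws 2237670 nuclear counts from each library. All 20 libraries were used unless the text says otherwise, and no other sequence or phenotype data were used here.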

Results

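Liver RNA was sequenced from C57BL/6 mice kept on a standard chow (10 libraries, chow 1 to 10) or on a high-fat diet (HFD, 10 libraries, HFD 1 to 10). Fat made up 60% of the HFD, with protein and carbohydrate at 20% each, and it was fed for 12 weeks. All 20 livers carry the genotype label WT, and the comparison asks how liver gene expression differed between the diets. Library totals ranged from 34727227 to 49065587 counts in chow and from 20111896 to 90033879 in HFD. HFD 1 and HFD 2 differed from the other libraries in content. Counts from the mitochondrial genome made up 75.6% of HFD 1 (95% Wilson interval 75.56% to 75.60%) and 94.4% of HFD 2 (94.43% to 94.44%), against 1.34% to 3.10% in the other libraries. Without mitochondrial and rRNA counts, 2237670 counts remained in HFD 1 and 2860976 in HFD 2. Annotated nuclear rRNA took 20.4% of the counts of chow 9 (20.37% to 20.40%) and 13.3% of those of HFD 1 (13.28% to 13.31%), and at most 0.807% of any other library. These intervals cover counting error only. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had counts in all 20 libraries, and Xist, the RNA that silences an X chromosome in females, had 45 counts in HFD 10 and none elsewhere.

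**Figure D1:**
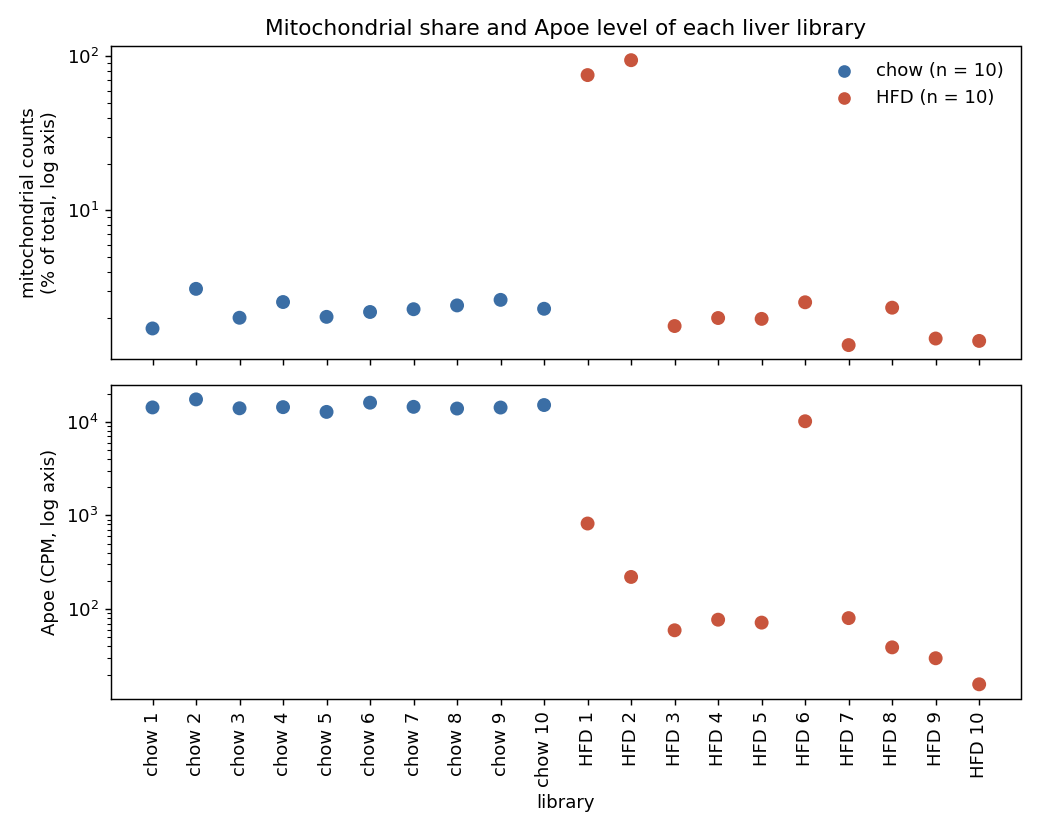
Share of counts from the mitochondrial genome (upper panel, percent of the library total, log axis) and level of Apoe (lower panel, CPM after TMM scaling, log axis) in each of the 20 libraries; blue points are chow and red points HFD. HFD 1 and HFD 2 lie at 75.6% and 94.4% mitochondrial counts, and Apoe lies between 15.7 and 819 CPM in every HFD library except HFD 6, where it is 10124 CPM.

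HFD livers had lower levels of cholesterol synthesis transcripts and higher levels of macrophage and neutrophil transcripts than chow livers. Sqle, which encodes squalene epoxidase of the sterol pathway, fell from 111 ± 23.5 CPM (mean ± SD, n = 10) to 12.8 ± 20.6 CPM (n = 10). Gpnmb, a marker of lipid-laden macrophages, rose from 0.197 ± 0.173 to 121 ± 90.6 CPM. Lcn2, the acute phase protein lipocalin, rose from 5.22 ± 3.16 to 504 ± 734 CPM. Apoe, which encodes apolipoprotein E, fell from 14606 ± 1269 to 1154 ± 3161 CPM. Differences in Apoe genotype or between pooled HFD groups were not tested, so these changes cannot be assigned to the diet alone. Of 14542 genes tested, 1886 were higher and 1025 lower in HFD at an adjusted p under 0.05 (edgeR quasi-likelihood test), so that 64.8% of the 2911 changed genes rose. This share depended on the method: it was 48.7% with limma voom, 48.9% with voom and sample quality weights and 69.3% with DESeq2. At least 2-fold changes numbered 1422 upward and 257 downward. With HFD 1 and HFD 2 left out, 2651 genes were higher and 1539 lower, and of the 2911 genes 2530 were called again in the same direction and 15 in the opposite one. Scaling by library totals alone, which leaves the mitochondrial counts of HFD 1 and HFD 2 in the scale, gave 600 changed genes, 84.5% of them higher, and ended the calls of 39 of the 114 genes whose values are given here.

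The largest rises among genes with a mean of at least 1 CPM included Gpnmb (593-fold; chromosome 6, 49036546 to 49070929, GRCm38), Cyp2a4 (178-fold; chromosome 7, 26307169 to 26315088), Saa2 (136-fold), Chil3 (104-fold) and Lcn2 (96.4-fold; chromosome 2, 32384633 to 32388252). Gpnmb and Cyp2a4, a steroid hydroxylase more abundant in female liver, were above the highest chow library in 10 of 10 HFD libraries. Cyp2a4 rose by 7.48 on the log2 scale (SE 0.387, adjusted p = 3.34e-11), with a near-identical neighbour, Cyp2a5, with which it may share reads. Chil3, a chitinase-like protein of macrophages, rose by 6.70 in log2, and by 5.65 without HFD 6. Saa2, Saa1 and Lcn2 also depended on HFD 10 for part of their size: without it the log2 changes were 5.80, 4.31 and 5.75, against 7.08, 5.27 and 6.59 with it. The other 5 genes among the largest rises were mitochondrially encoded. In chow mt-Co2 and mt-Co3 were near the floor, at 0.169 ± 0.0926 and 0.591 ± 0.0914 CPM, against 1582 ± 217 and 919 ± 184 CPM for mt-Nd2 and mt-Nd4. The log2 changes of mt-Nd2, mt-Nd4, mt-Co2 and mt-Co3 were between 6.39 and 6.86 with all libraries. Without HFD 2 those of mt-Nd2, mt-Nd4, mt-Co2 and mt-Co3 were 4.97, 5.63, 5.87 and 5.66, and without HFD 1 those of mt-Nd4, mt-Co2 and mt-Co3 were 5.74, 6.06 and 6.24. With HFD 1 and HFD 2 both left out the 4 were −0.38, −0.46, −0.33 and −0.10, and mt-Nd2 and mt-Nd4 were called lower. mt-Nd3, at 0.105 ± 0.0906 CPM in chow, had a log2 change of 10.71 with all libraries, 10.07 without HFD 1, 9.67 without HFD 2 and 3.80 with both left out (adjusted p = 9.54e-06), and shares sequence with nuclear copies.

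The largest falls were of Apoe (12.7-fold), Idi1 (11.2-fold; chromosome 13, 8885501 to 8892451), Ugt2b38 (9.02-fold), Msmo1 (8.59-fold; chromosome 8, 64718139 to 64733792), Sqle (8.57-fold; chromosome 15, 59315077 to 59331192), Cyp51 (8.31-fold), Mup-ps20 (7.89-fold), Gpx6 (7.85-fold), Mvd (7.85-fold) and Cyp2c55 (7.78-fold). Idi1, Msmo1, Sqle, Cyp51 and Mvd encode enzymes of cholesterol synthesis. Ugt2b38 is a glucuronosyltransferase, Cyp2c55 a cytochrome P450, and Mup-ps20 a pseudogene in the major urinary protein cluster whose reads cannot be separated from its relatives with certainty. Sqle was 70.7 CPM in HFD 10 and between 2.54 and 12.6 CPM in the other 9 HFD libraries, and its log2 change of −3.10 became −4.12 without HFD 10.

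Apoe (chromosome 7, 19696109 to 19699188), the ligand by which lipoprotein remnants are taken up, fell by 3.66 on the log2 scale (SE 1.03, adjusted p = 0.0155). Chow libraries ranged from 12739 to 17328 CPM. All 10 HFD libraries lay below that range, HFD 6 at 10124 CPM and the other 9 between 15.7 and 819 CPM. Without HFD 6 the log2 change was −6.55 (adjusted p = 7.16e-07), and with library totals alone the call was lost (log2 change −3.49, adjusted p = 0.0584). The WT label was not tested here, so a fall of Apoe with the diet cannot be told from a difference in Apoe genotype between the groups. Of the 21 tested members of the lipoprotein and cholesterol transport list 5 rose and 5 fell (6 and 7 adjusted over the list alone; median log2 change −0.17, camera adjusted p = 0.862). The cholesterol exporter Abcg1 rose from 7.01 ± 1.28 to 34.1 ± 11.9 CPM (log2 change 2.29, SE 0.214, adjusted p = 1.38e-07). Apoa4 rose from 17.0 ± 3.14 to 130 ± 224 CPM, a log2 change of 2.94 that was 1.85 without HFD 6.

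Genes of the sterol synthesis list fell as a group. Of 24 tested members 23 fell and none rose (24 fell when adjusted over the list alone), with a median log2 change of −2.05 and a camera adjusted p of 1.72e-44, which was 0.00461 with an estimated correlation. Hmgcs1, which makes the HMG-CoA used for sterols, fell from 348 ± 114 to 51.2 ± 21.4 CPM and was below every chow library in 10 of 10 HFD libraries (log2 change −2.77, SE 0.246, adjusted p = 5.86e-08; chromosome 13, 119690379 to 119708260). Mvd, which acts later in the pathway, fell from 23.1 ± 6.38 to 2.82 ± 1.41 CPM, and Msmo1 from 318 ± 48.9 to 36.9 ± 19.7 CPM.

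**Figure D2:**
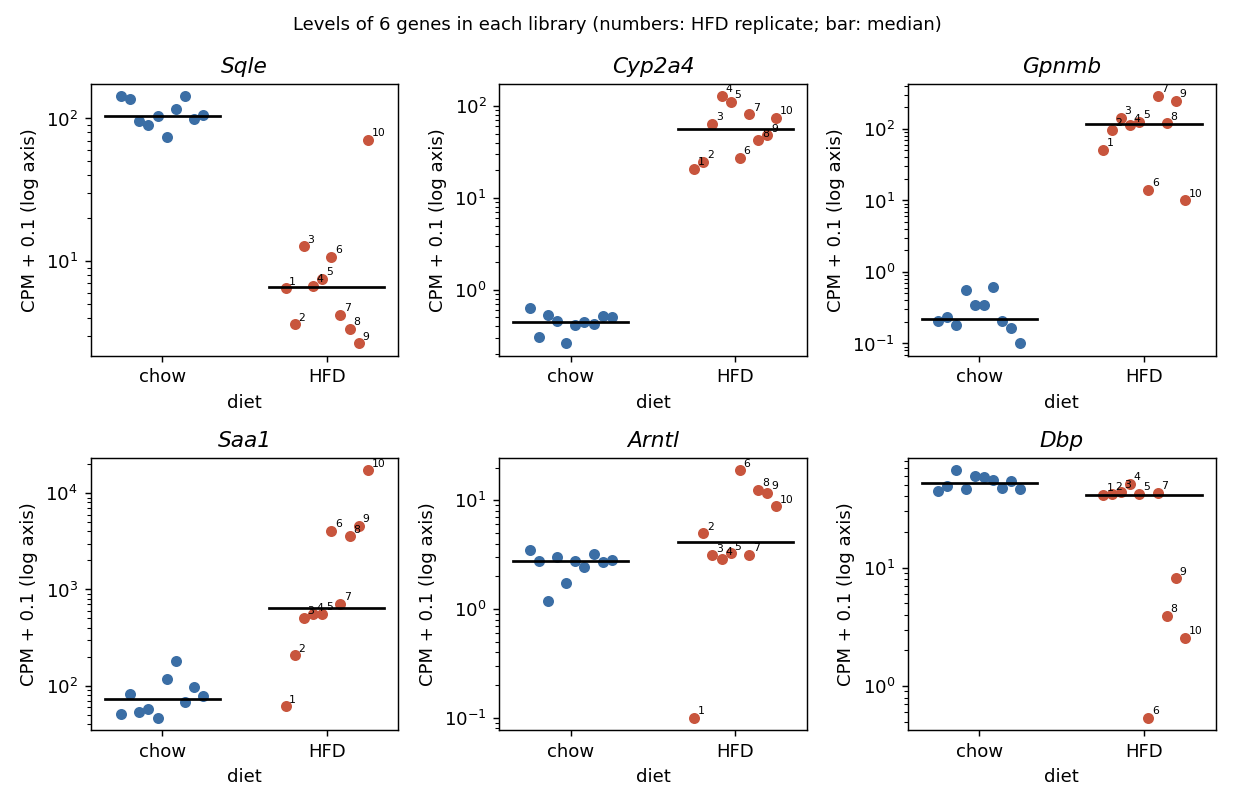
Levels of Sqle, Cyp2a4, Gpnmb, Saa1, Arntl and Dbp in each library (CPM after TMM scaling plus 0.1, log axis); each point is a library, with chow in blue and HFD in red, small numbers name the HFD replicate and the bar is the group median. Sqle in HFD 10 is 70.7 CPM, and Arntl is 18.7, 12.3, 11.6 and 8.71 CPM in HFD 6, 8, 9 and 10.

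Fatty acid synthesis genes were lower as a list, with 8 of 18 tested members lower and 1 higher (the same counts adjusted over the list alone; median log2 change −0.42, camera adjusted p = 7.40e-05, adjusted p = 0.346 with an estimated correlation). Acss2 and Acly, which make cytosolic acetyl-CoA, fell by 1.85 and 1.24 in log2. Fasn, the fatty acid synthase, fell from 268 ± 114 to 146 ± 29.1 CPM (adjusted p = 0.00363). Scd1, the stearoyl-CoA desaturase, was at 7228 ± 2931 CPM in chow and 10221 ± 2375 CPM in HFD and did not pass the test (adjusted p = 0.142), though with HFD 1 and HFD 2 left out it rose by 0.61 in log2 (adjusted p = 0.0419). The lipogenic regulator Srebf1 was at 140 ± 23.5 and 124 ± 38.8 CPM (adjusted p = 0.528).

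Genes of fatty acid oxidation and PPARA targets split, with 3 of 30 tested members higher and 6 lower (3 and 9 adjusted over the list alone). Their median log2 change was −0.37 and the camera adjusted p 0.0227, or adjusted p = 0.691 with an estimated correlation. This list call was lost without HFD 2 (adjusted p = 0.0689), without HFD 10 (adjusted p = 0.0598) and without HFD 1 and HFD 2 together (adjusted p = 0.0950). Acsl1 and Acaa2, of fatty acid activation and mitochondrial oxidation, fell by 0.99 and 0.75 in log2. Cyp4a14, a fatty acid hydroxylase induced by PPARA that has close paralogs, rose from 27.1 ± 26.1 to 216 ± 263 CPM (adjusted p = 0.00807). The higher HFD mean rested on HFD 6, 7 and 9 (613, 540 and 628 CPM) and HFD 8 (114 CPM). In HFD 1, 2, 3, 4, 5 and 10 it was 16.8 to 56.8 CPM, within the chow range of 4.97 to 73.1 CPM. Cpt1a, which carries fatty acids into mitochondria, was at 331 ± 30.5 and 285 ± 114 CPM (adjusted p = 0.553), and Fgf21, a hormone of fasting liver, at 0.592 ± 0.555 and 1.35 ± 1.64 CPM (adjusted p = 0.228).

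In the lipid droplet and lipid uptake list 6 of 20 tested members rose and 5 fell (the same adjusted over the list alone; median log2 change −0.24, camera adjusted p = 0.972). The fatty acid transporter Cd36 rose from 37.2 ± 10.9 to 110 ± 42.2 CPM, lipoprotein lipase Lpl from 20.3 ± 5.54 to 197 ± 176 CPM and Fabp4, a lipid chaperone, from 5.13 ± 1.32 to 17.8 ± 8.41 CPM. Lpl (log2 change 3.28, SE 0.369) was above every chow library in 10 of 10 HFD libraries and changed by 2.59 with HFD 1 and HFD 2 left out. Hilpda rose by 2.91 in log2, and by 1.61 without HFD 6. The lipid droplet coat gene Plin2 was at 389 ± 59.5 and 284 ± 97.7 CPM (adjusted p = 0.121). Cidec, of lipid droplet fusion, was at 2.39 ± 0.814 and 3.45 ± 5.05 CPM (adjusted p = 0.417); the higher HFD mean rested on HFD 6 (17.5 CPM), without which the log2 change went from 0.57 to −0.29. Cidea, with 126 counts over the chow and 115 over the HFD libraries, was too low to test. The adipogenic regulator Pparg was at 13.2 ± 2.17 and 9.37 ± 3.93 CPM (adjusted p = 0.272), and with HFD 1 and HFD 2 left out it fell by 0.39 in log2 (adjusted p = 0.0145).

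Bile acid synthesis and transport genes were lower as a list, with 5 of 20 tested members lower and 1 higher (8 and 1 adjusted over the list alone; median log2 change −0.65, camera adjusted p = 0.000320, adjusted p = 0.470 with an estimated correlation). Cyp7b1, of the alternative bile acid pathway, fell from 455 ± 67.9 to 131 ± 88.9 CPM, and Slc10a1, the bile acid uptake transporter, from 592 ± 47.4 to 299 ± 154 CPM. Cyp8b1, the sterol hydroxylase that makes cholic acid, had a log2 change of −1.07 (adjusted p = 0.0438) that lost its call when any of chow 2 to 10 or HFD 1, 4, 7, 8 or 10 was left out (adjusted p up to 0.0722, without chow 10). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 34.3 ± 18.7 and 57.3 ± 41.6 CPM (adjusted p = 0.287).

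Drug-metabolising cytochromes P450 were lower as a list, with 5 of 18 tested members lower and 1 higher (9 and 2 adjusted over the list alone; median log2 change −0.79, camera adjusted p = 0.0173, adjusted p = 0.527 with an estimated correlation). The list call was lost with HFD 1 and HFD 2 left out (adjusted p = 0.110). Cyp2c29 fell from 1772 ± 291 to 543 ± 301 CPM, with close paralogs that may share its reads. In the glutathione and NRF2 target list 5 of 22 tested members rose and 8 fell (the same adjusted over the list alone; median log2 change −0.24, camera adjusted p = 0.119). Haem oxygenase Hmox1 rose from 22.9 ± 4.61 to 110 ± 92.9 CPM and G6pdx, of NADPH production, by 1.47 in log2, whereas the glutathione transferase Gstm4 fell by 0.85.

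Amino acid, urea and methionine metabolism was lower as a list, with 10 of 26 tested members lower and none higher (10 adjusted over the list alone; median log2 change −0.51, camera adjusted p = 5.42e-06, adjusted p = 0.346 with an estimated correlation). Gnmt, which consumes S-adenosylmethionine, fell from 1693 ± 146 to 776 ± 277 CPM, and Hal, the histidine ammonia-lyase, from 444 ± 66.2 to 233 ± 65.6 CPM. Nuclear-encoded respiratory chain genes fell, 23 of 30 tested members and none rising (27 adjusted over the list alone; median log2 change −0.52, camera adjusted p = 5.59e-09, adjusted p = 0.346 with an estimated correlation). With library totals alone 0 of the 30 were called (median −0.53). Among them Ndufv1 of complex I changed by −0.62 and Uqcrc1 of complex III by −0.64 in log2. In the glucose production and insulin response list 2 of 18 tested members rose and 1 fell (the same adjusted over the list alone; median log2 change −0.07, camera adjusted p = 0.510). The gluconeogenic Pck1 was at 1681 ± 473 and 1564 ± 339 CPM (adjusted p = 0.726) and G6pc at 152 ± 80.5 and 195 ± 274 CPM (adjusted p = 0.644). The higher HFD mean of G6pc rested on HFD 6 (958 CPM), without which its log2 change went from 0.36 to −0.47. Igfbp1, an insulin-repressed secreted protein, rose from 15.1 ± 7.30 to 318 ± 767 CPM, a log2 change of 4.40 that was 2.37 without HFD 6, where it reached 2478 CPM.

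Male-biased liver genes were lower as a list, with 11 of 20 tested members lower and none higher (13 adjusted over the list alone; median log2 change −1.36, camera adjusted p = 9.54e-11, adjusted p = 0.303 with an estimated correlation). Elovl3, a fatty acid elongase, fell from 269 ± 43.0 to 103 ± 70.7 CPM, Cyp4a12a by 2.14 in log2 and Gstp1 from 1247 ± 182 to 512 ± 201 CPM. Hsd3b5, a male-specific hydroxysteroid dehydrogenase, was at 459 ± 67.7 and 133 ± 102 CPM and below every chow library in 10 of 10 HFD libraries but did not pass the test (adjusted p = 0.0681); it was called without HFD 6 (adjusted p = 0.0266) or without HFD 10 (adjusted p = 0.0450), where it was 0.192 and 0.664 CPM. Of 9 tested female-biased genes 2 rose and 2 fell (4 and 3 adjusted over the list alone; median log2 change 0.41, camera adjusted p = 0.419), Cyp2a4 upward and Cyp2g1 downward by 2.04 in log2. Cyp2b9 had 40 counts over the chow and 191 over the HFD libraries and was not tested.

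Among growth hormone targets and circulating liver factors 2 of 22 tested members rose and 3 fell (2 and 5 adjusted over the list alone; median log2 change −0.27, camera adjusted p = 0.141). Lepr, the leptin receptor, rose from 1.17 ± 0.453 to 29.6 ± 74.2 CPM, a log2 change of 4.67 that was 2.42 without HFD 6, where it reached 240 CPM. Igfals, which stabilises circulating IGF1, fell from 81.6 ± 11.8 to 40.7 ± 16.7 CPM. In the clock list 3 of 19 tested members rose and 4 fell (3 and 5 adjusted over the list alone; median log2 change 0.09, camera adjusted p = 0.324 with the direction down). The clock activators Arntl and Npas2 rose by 1.47 and 2.16 in log2, and Bhlhe41 and Cry2, clock repressors, fell by 1.57 and 0.75. The calls of Arntl and Npas2 were lost with HFD 6, 8, 9 and 10 left out (log2 changes 0.22 and 1.06, adjusted p = 0.673 and 0.0715), and that of Arntl also with limma voom (adjusted p = 0.106) and with library totals alone (adjusted p = 0.144). HFD 6, 8, 9 and 10 hold the highest HFD values of both genes, so leaving them out had to lower both changes. Of 22 tested members of the unfolded protein and integrated stress response 3 rose, among them Ddit3, and 2 fell, among them Xbp1 (the same counts adjusted over the list alone; median log2 change −0.16, camera adjusted p = 0.335).

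Acute phase protein genes rose, 15 of 25 tested members with none falling (18 higher and 1 lower adjusted over the list alone; median log2 change 1.38, camera adjusted p = 4.37e-08, adjusted p = 0.354 with an estimated correlation). The size depended on which HFD libraries were kept. With HFD 6, 8, 9 and 10 left out 8 members were higher and 1 lower, the median was 0.27 (camera adjusted p = 7.40e-05) and the log2 change of Saa1 was 2.39. HFD 6, 8, 9 and 10 have the highest Saa1 levels and acute phase scores in HFD, so leaving them out was bound to lower this size. That refit also keeps HFD 1 and HFD 2, with scores of −1.19 and −0.82 against −1.17 to −0.37 in chow. HFD 3, 4, 5 and 7 scored 0.33, 0.48, 0.43 and 0.83, above every chow library. With HFD 1 and HFD 2 left out 23 of 25 members were higher and 0 lower (median 1.70). Saa1, serum amyloid A (chromosome 7, 46740497 to 46742980), rose from 83.0 ± 40.4 to 3203 ± 5221 CPM and lay above every chow library in 9 of 10 HFD libraries; it shares long stretches of sequence with Saa2. Orm3, an acid glycoprotein with close paralogs, rose by 4.25 and Il1rn, the interleukin-1 receptor antagonist, by 3.61 in log2. Interferon response genes numbered 4 higher and 1 lower of 27 (6 and 1 adjusted over the list alone; median log2 change 0.53, camera adjusted p = 0.0943), and the list passed the test without HFD 6 (adjusted p = 0.00496) or HFD 10 (adjusted p = 0.0419), or without chow 4 or chow 6 (adjusted p = 0.0361 and 0.0486). With HFD 6, 8, 9 and 10 left out 14 were higher and 0 lower (median 0.84), without HFD 1, 2 and 6 9 were higher, and without HFD 1 and 2 3 were (median 0.20). Gbp2 and Cxcl10 of that list rose by 1.56 and 1.26 in log2.

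Markers of recruited and lipid-associated macrophages rose, 19 of 21 tested members with none falling (19 adjusted over the list alone; median log2 change 2.75, camera adjusted p = 2.09e-31, 1.52e-07 with an estimated correlation). Trem2, a lipid receptor of such macrophages, rose from 0.449 ± 0.212 to 15.5 ± 8.05 CPM in 10 of 10 libraries above chow (chromosome 17, 48346401 to 48354147). Lyz2, the macrophage lysozyme, rose from 83.8 ± 12.7 to 491 ± 151 CPM, and the elastase Mmp12 from 0.361 ± 0.182 to 29.9 ± 12.8 CPM. Resident Kupffer cell markers rose in 10 of 15 tested members with none falling (10 adjusted over the list alone; median log2 change 1.09, camera adjusted p = 5.92e-09, adjusted p = 0.0519 with an estimated correlation). The scavenger receptor Marco rose from 8.20 ± 4.25 to 152 ± 174 CPM, a log2 change of 4.22 that was 3.60 without HFD 6. Cd5l rose from 179 ± 46.0 to 758 ± 256 CPM, C1qb of complement by 1.32 in log2, and Adgre1, the F4/80 antigen, from 23.8 ± 6.88 to 49.0 ± 14.9 CPM.

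Neutrophil markers rose in all 8 tested members (8 adjusted over the list alone; median log2 change 3.63, camera adjusted p = 8.45e-12, 0.0357 with an estimated correlation). With HFD 1 and HFD 2 left out the p with an estimated correlation was 0.191. When 1 library was left out the median ranged from 2.95, without chow 10, to 4.24, without chow 6, and it was 2.82 with HFD 6, 8, 9 and 10 left out. S100a9 and S100a8, the calprotectin subunits, rose from 1.25 ± 0.231 to 49.8 ± 57.8 CPM and from 0.994 ± 0.166 to 29.5 ± 36.2 CPM. The log2 change of S100a8 was 4.88, and 4.26 without HFD 10. The granulocyte receptor Csf3r and the cytokine Il1b rose by 2.31 and 2.67 in log2. MHC class II and antigen presentation genes rose, 8 of 12 with none falling (8 adjusted over the list alone; median log2 change 1.16, camera adjusted p = 0.00104, adjusted p = 0.476 with an estimated correlation), with Ctss from 47.4 ± 12.0 to 130 ± 20.7 CPM and H2-Aa from 42.6 ± 6.56 to 106 ± 52.6 CPM. Library totals alone gave 0 of the 12 called (median 0.98). Lymphocyte markers rose in 9 of 21 tested members (13 adjusted over the list alone; median log2 change 1.23, camera adjusted p = 0.00655, adjusted p = 0.612 with an estimated correlation), among them Ccl5 and Cd22. This list call was lost without HFD 8 (median log2 change 0.69, adjusted p = 0.0977) and with HFD 1 and HFD 2 left out (adjusted p = 0.0847).

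**Figure D3:**
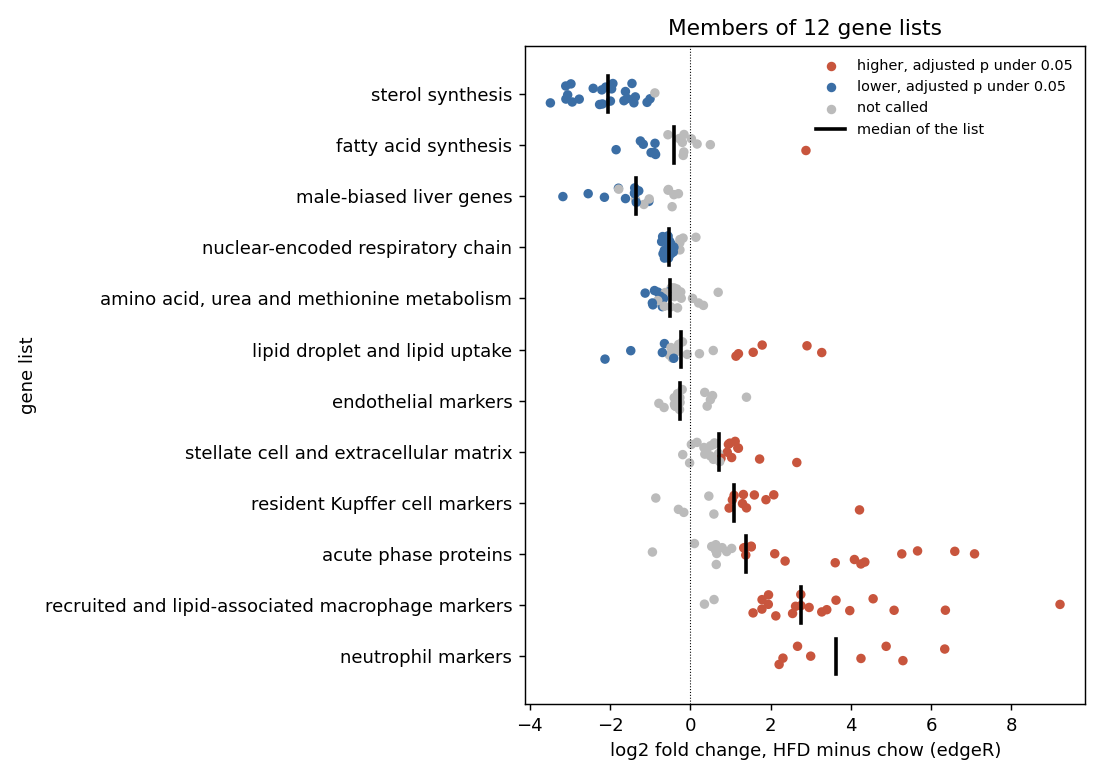
Log2 fold changes (HFD minus chow, edgeR) of the tested members of 12 gene lists; each point is a gene, red if higher and blue if lower at an adjusted p under 0.05, grey if not called, and the black bar is the list median. The sterol synthesis list has a median of −2.05, recruited and lipid-associated macrophage markers one of 2.75 and neutrophil markers one of 3.63.

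Stellate cell and extracellular matrix genes rose, 10 of 25 tested members with none falling (11 adjusted over the list alone; median log2 change 0.71, camera adjusted p = 6.12e-05, adjusted p = 0.354 with an estimated correlation). The type I collagen genes Col1a1 and Col1a2 rose from 4.09 ± 1.43 to 13.8 ± 11.5 CPM and from 9.00 ± 2.62 to 20.8 ± 10.5 CPM. In the refit without HFD 1 and HFD 2, 23 of 26 tested members of this list were higher (median 0.81), and without HFD 6 as well 22 of 26 were. Thbs1 rose by 2.65 and the profibrotic cytokine Tgfb1 by 1.03 in log2. None of 17 endothelial markers passed the test, over all genes or over the list alone (median log2 change −0.27, camera adjusted p = 0.442). In the refit without HFD 1 and HFD 2, 4 of the 17 were called higher (median −0.073), and without HFD 6 as well 5 were (median −0.074). Cdh5, the vascular cadherin, was at 31.7 ± 7.78 and 44.7 ± 15.6 CPM (adjusted p = 0.109) and was called higher without HFD 1 (adjusted p = 0.0211), without HFD 2 (adjusted p = 0.0277) and without both (adjusted p = 0.000561). Of 10 cholangiocyte markers 1, Sox9, rose (1 adjusted over the list alone; median log2 change −0.37, camera adjusted p = 0.471).

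Hepatocyte identity genes were lower as a list, with 3 of 20 lower and none higher (3 adjusted over the list alone; median log2 change −0.43, camera adjusted p = 0.000904, adjusted p = 0.522 with an estimated correlation). Transthyretin, Ttr, fell from 6584 ± 1153 to 3087 ± 1124 CPM and the tryptophan dioxygenase Tdo2 from 1689 ± 114 to 859 ± 431 CPM. Of 18 pericentral genes 1 rose and 1 fell (none adjusted over the list alone; median log2 change −0.26, camera adjusted p = 0.0668). Of 16 periportal genes 3 rose and 4 fell (the same adjusted over the list alone; median log2 change −0.32, camera adjusted p = 0.0668), Ctsc upward and Etnppl downward by 1.64 in log2. Both zonation lists passed the camera test in some refits without 1 library, the pericentral list without HFD 4, 5, 7 or 8 (adjusted p = 0.0267, 0.0334, 0.0478 and 0.0499) and the periportal list without chow 5, HFD 7 or HFD 10 (adjusted p = 0.0465, 0.0478 and 0.0436). The glutathione and NRF2 list did so without HFD 6 (adjusted p = 0.0228).

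Immediate early and heat shock genes rose, 9 of 16 with none falling (11 adjusted over the list alone; median log2 change 0.76, camera adjusted p = 8.90e-06, 0.0357 with an estimated correlation). Atf3, a stress-induced transcription factor, rose from 0.957 ± 0.247 to 13.4 ± 11.3 CPM, and the immediate early genes Fos and Jun rose by 2.13 and 1.40 in log2. With HFD 1 and HFD 2 left out the p with an estimated correlation was 0.135. Proliferation genes were higher as a list, with 2 of 19 higher and none lower (1 adjusted over the list alone; median log2 change 0.64, camera adjusted p = 0.0197, adjusted p = 0.527 with an estimated correlation). One of the 2 was Cdkn1a, which encodes an inhibitor of the cell cycle and rose from 1.57 ± 0.415 to 14.2 ± 16.0 CPM.

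Blood cell markers numbered 6 higher of 9 (8 adjusted over the list alone; median log2 change 2.11, camera adjusted p = 0.0798). The globin genes Hba-a1 and Hbb-bs, with log2 changes of 2.37 and 2.00, were not called without HFD 2 (1.48 and 1.05, adjusted p = 0.107 and 0.169), and Hbb-bs also lost its call without HFD 1 or any of chow 3 to 10, and Hba-a1 without chow 5, 7, 9 or 10. The platelet chemokine Ppbp rose by 3.87 in log2, by 2.92 without HFD 2 and by 1.45 with HFD 1 and HFD 2 left out. The list median was 1.46 without HFD 2, and the list passed the test without chow 1, 2, 3, 4, 5, 6, 9 or 10 or HFD 3, 4, 5, 7 or 8 (adjusted p from 0.0104 to 0.0478). All 11 tested mitochondrially encoded genes were called higher (11 adjusted over the list alone; median log2 change 6.33, camera adjusted p = 0.0630). The camera test passed without HFD 3, 4, 5, 7, 8, 9 or 10 (adjusted p from 0.0274 to 0.0384), the median was 4.97 without HFD 2, and with HFD 1 and HFD 2 left out it was −0.45 with 1 member higher and 6 lower. Cytosolic ribosomal protein genes had 3 of 30 members higher (none adjusted over the list alone; median log2 change 0.18, camera adjusted p = 0.326), and with HFD 1 and HFD 2 left out 1 was higher and 2 lower (median −0.12); most have processed pseudogenes that may take reads.

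Adipocyte markers had 2 of 8 tested members higher and 1 lower (the same adjusted over the list alone; median log2 change 0.37, camera adjusted p = 0.815). With too few tested members for a list test, pancreas markers had 1 of 2 lower, the elastase Cela1 (41.9 ± 13.7 to 13.4 ± 6.21 CPM), and the 1 tested skeletal muscle marker was not called over all genes. Of the 35 lists tested, 9 were higher and 9 lower, and with an estimated correlation 4 of the 18 kept their call: sterol synthesis, recruited macrophages, neutrophils and immediate early genes. Mean and median differed in sign for lipid droplet, lipoprotein, glucose, glutathione, growth hormone and stress response genes, with means of 0.25, 0.16, 0.41, 0.09, 0.21 and 0.04. The camera direction was that of the mean for lipid droplets and that of the median for the others of these; for the clock list the mean, 0.15, and the median were above 0 and the direction was down.

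On average, HFD livers lay farther from their group mean than chow livers did. The study's design text speaks of 3 groups on the HFD, which the labels do not tell apart, and pooling such groups would by itself widen these distances and scores. The mean Euclidean distance of a library to its group mean, over the 2000 tested genes with the highest expression in log2 CPM, was 31.8 ± 17.1 in HFD and 9.38 ± 3.69 in chow (n = 10 each), a difference of 22.5 (two-sided permutation test, p = 3e-05). HFD 6, HFD 1 and HFD 2 lay farthest, at distances of 58.0, 56.7 and 53.3, against 6.03 to 17.1 in chow. The few nuclear counts of HFD 1 and HFD 2 add counting noise to their distances. With HFD 1 and HFD 2 left out the difference was 11.9 (exact permutation test, n = 8 and 10, p = 0.00135). HFD 6 was not left out together with them, so this difference may rest on it in part. The scores of 8 of 35 gene lists varied more in HFD after Benjamini-Hochberg adjustment over the lists, and none varied less: sterol synthesis, bile acids, glutathione and NRF2 targets, male-biased genes, clock genes, acute phase proteins, MHC class II and neutrophils. Mean absolute deviations from the group median were 0.320 in HFD and 0.0816 in chow for clock genes (permutation test, p = 0.00013, adjusted p = 0.00455) and 0.963 and 0.174 for acute phase proteins (permutation test, p = 0.00299, adjusted p = 0.0215). With HFD 1 and HFD 2 left out 7 of the 8 held, all but bile acids. With log2(FPKM + 1) sterol synthesis and bile acids did not pass (permutation tests, adjusted p = 0.0889 each), and P450 (adjusted p = 0.0264) and lymphocytes (adjusted p = 0.0183) did.

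The lipid droplet and lipid uptake score was compared within each diet with the scores of 5 other lists, and none of these 10 relations passed adjustment (permutation tests, n = 10 libraries each). The largest in HFD was with the extracellular matrix list (Pearson r = 0.70, p = 0.0283, adjusted p = 0.157; Spearman rho = 0.13, p = 0.731, adjusted p = 0.973). Without the 2 libraries farthest from the median lipid droplet score, HFD 1 and HFD 2, it was r = −0.68 (exact permutation test, n = 8, p = 0.0620), so the positive r rested on those 2 libraries. In chow, fatty acid synthesis had r = 0.66 (p = 0.0375, adjusted p = 0.157; rho = 0.52, p = 0.133) and male-biased genes r = −0.64 (p = 0.0470, adjusted p = 0.157; rho = −0.54, p = 0.114), which were 0.54 and −0.10 without the 2 farthest libraries. The other 7 relations had unadjusted p-values from 0.0906 to 0.927.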

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

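The tests of explanations in this part were all chosen only after the results were seen. A library is listed here when the gap between it and its nearest neighbour is a large part of the range of its 10 libraries (Dixon's ratio of gap to range). Chance alone marks about 1 in 20 groups, and 45 of 308 groups were marked, 14 of them by HFD 6, 12 by HFD 1 and 10 by chow 2. The Apoe level and the mitochondrial share, taken up next, were not among the marked groups. Of 100 splits of the 20 libraries into 10 and 10, only 1, the real one, gave as many calls as the diets (2911, highest other 1). The same held for larger changes (1 of 100, 1679, highest other 1). A share of 1 of 100 is the smallest that these splits can give, so they do not exclude chance. The other splits mixed the diets within each group, which widens the spread within groups, so few calls were likely in advance. The splits cannot tell the diet from a difference in handling, genotype or unlabelled groups.

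Apoe lay below the chow range in all HFD livers, and in 9 of 10 it was at most 5.61% of the chow mean, whereas HFD 6 had 69.3% of it. HFD 1 and HFD 2, with few nuclear counts, had 5.61% and 1.51%. In the HFD livers other than HFD 1, HFD 2 and HFD 6 it was nearly absent, from 0.108% (HFD 10) to 0.548% (HFD 7). Although all samples are labelled WT, the HFD mice may differ from the chow mice in Apoe genotype. This was not tested and stays open, and it would change what the fall of Apoe and the whole comparison of diets mean. The size of the fall cannot decide it, since no livers of tested Apoe genotype were compared. That HFD 6 is a chow liver with a wrong label is argued against by the other genes, since 66.6% of 3108 genes called without HFD 6 lie nearer the HFD median in HFD 6. A chromosome segment of other origin around Apoe could change its neighbours as well: within 5 Mb 12 of 25 called genes other than Apoe lie nearer chow in HFD 6 (48.0%), which is percentile 89.3 of 2227 windows elsewhere (median 34.2%, 95th percentile 54.5%) and leaves this open. The level in HFD 6 cannot tell whether the diet alone lowers Apoe.

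The mitochondrial share of HFD 1 and HFD 2 was 75.6% and 94.4%. A rise caused by the diet is argued against, since 0 of the other 8 HFD libraries lie above the highest chow library. Few nuclear RNA molecules could leave fewer genes detected at equal nuclear depth: HFD 1 had 11980 genes, fewer than every other library, and this fits. HFD 2 had 14188, below the other 8 HFD libraries (14512 to 15506) but within the chow range (13839 to 14652), so for HFD 2 it stays open.

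Macrophage and neutrophil markers were higher in HFD. A lower share of hepatocytes could raise the markers of all other cells alike, but the recruited macrophage median exceeded the endothelial one by 3.02 in log2. The 95% bootstrap interval was 2.20 to 3.72. This interval resamples list members and not livers, so it leaves out the spread between livers. With HFD 1 and HFD 2 left out, where 4 of 17 endothelial markers were called higher, the medians were 2.49 and −0.073. More blood in the HFD livers could raise neutrophil and globin transcripts together. With HFD 1 and HFD 2 left out the neutrophil median was 3.43 and exceeded the larger globin change, 0.46 for Hba-a1, by 2.98. This argues against more blood of unchanged composition as the whole source of the neutrophil rise, but not against a part. Globin levels do not measure the share of neutrophils in the blood, so a rise of that share was not tested. HFD 1, 2, 6 and 10 had the highest HFD levels of both S100a9 (at least 33.03 CPM) and Hba-a1 (at least 349 CPM). In the other HFD libraries Hba-a1 was at most 104 CPM, and S100a9, at most 25.5 CPM, still exceeded every chow library. A contribution of blood to the size of the neutrophil rise stays open. The macrophage calls did not rest on HFD 1 and HFD 2, since 100% of 19 called members stayed called higher without them. Bulk RNA cannot separate more cells from more transcript per cell.

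Ratios of the marked groups, given as values, were as follows. Nuclear rRNA was highest in chow 9 (0.966) and, in HFD, in HFD 1 (0.986), and the number of genes at equal depth was lowest in HFD 1 (0.626). Among list scores, HFD 6 was lowest for fatty acid synthesis (0.746) and MHC class II (0.607) and highest for glutathione and NRF2 targets (0.491), and HFD 1 was lowest for proliferation genes (0.523). Chow 2 was lowest for bile acids (0.544), the extracellular matrix (0.5606) and endothelial markers (0.708) and highest for ribosomal proteins (0.5613). Chow 1 was highest for MHC class II (0.467) and lowest for mitochondrially encoded genes (0.559), and chow 7 highest for cholangiocyte markers (0.765).

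Among single genes HFD 6 was lowest for Srebf1 (0.493), Cyp7a1 (0.606), Igfals (0.518), H2-Aa (0.599), Cd5l (0.576), Trem2 (0.498) and Lyz2 (0.467), and highest for G6pc (0.477), Hmox1 (0.577), Lepr (0.596) and Jun (0.478). HFD 1 was lowest for Relb (0.830), Chil3 (0.502), Pparg (0.892), Cyp2g1 (0.467), Arntl (0.698), Bhlhe41 (0.527), Adgre1 (0.552) and Tgfb1 (0.737) and highest for Uty (0.563). HFD 10 was highest for Sqle (0.521) and lowest for Mmp12 (0.752). Chow 2 was lowest for Cd36 (0.553), Fabp4 (0.649), Col1a1 (0.534), Col1a2 (0.542) and Cdh5 (0.564) and highest for Ttr (0.591). Chow 4 was lowest for Relb (0.499), chow 10 lowest for Tdo2 (0.496) and chow 8 highest for Ppbp (0.474).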

How the results depend on the processing

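Of 114 genes with printed values 97 were called, and 94 of these kept their call in every refit without 1 library and 38 under every setting. Many of the 114 were named for small p-values or large changes, so this tally does not describe called genes in general. Calls ended for 39 genes with library totals alone, 50 with log2(FPKM + 1), 53 with log2(FPKM + 0.1), 11 with limma voom and 3 with no filter. FPKM carries the mitochondrial counts of HFD 1 and HFD 2 in its scale; otherwise the cause of each change below was not tested. Sign changes between values that were both not called are not compared. Depth limits HFD 1 and HFD 2 most, with 2237670 and 2860976 nuclear counts. Every alternative listed before the data were examined was run.

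Counts of changed genes (2911) moved by over 1.5 times to 4429 with DESeq2, 5335 with voom and quality weights, 600 with library totals alone, 717 with log2(FPKM + 1), 498 with log2(FPKM + 0.1) and 4964 without HFD 1, 2 and 6. Counts of at least 2-fold changes (1679) moved to 600, 261 and 435 with library totals alone and the 2 FPKM settings. Refits without 1 library gave 2424 (chow 6) to 3330 (HFD 1) changed genes, 1521 (chow 3) to 1817 (HFD 4) of at least 2-fold, 17 (HFD 2) to 22 (HFD 7) lists and a difference in spread of 17.6 (HFD 1) to 24.6 (HFD 8). The spread stayed wider in HFD with more genes in the measure (30.8), all tested genes (75.9) and 1 minus Spearman correlation (0.119). With log2(FPKM + 1), 7 relations between list scores passed by Pearson r against 0. That of lipid droplets with fatty acid synthesis in HFD turned from r = −0.41 to 0.90. Its Spearman rho went from −0.59 to 0.30 (permutation tests, adjusted p = 0.331 and 0.510). By Spearman rho no relation in HFD passed with log2(FPKM + 1).

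The replicate number shared by the diets does not pair the libraries: same-numbered deviations correlated at −0.11 to 0.13 (mean 0.022), over 0.1 in 2 of 10 pairs, and the own number was the best match in 2. With the replicate block 1574 genes changed, 1019 at least 2-fold, 14 genes with printed values lost their call and blood markers gained one (median 0.91); of 12 MHC class II genes 1 was then called (median 0.93) and of 30 respiratory chain genes 14.

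With an estimated correlation 4 of 18 lists stayed called. Those that did not, with their unchanged medians, are fatty acid synthesis (−0.42), fatty acid oxidation (−0.37), bile acids (−0.65), amino acids (−0.51), P450 (−0.79), male-biased (−1.36), respiratory chain (−0.52), acute phase (1.38), MHC class II (1.16), Kupffer cells (1.09), lymphocytes (1.23), extracellular matrix (0.71), hepatocyte identity (−0.43) and proliferation (0.64). With fry, fatty acid oxidation (−0.37) and lymphocytes (1.23) lost their call, and growth hormone (−0.27), clock (0.087) and periportal genes (−0.32) gained one. With library totals alone fatty acid oxidation (−0.31) and P450 (−0.61) lost it, and blood (0.67) and mitochondrially encoded genes (3.27) gained it. Fewer members were then called in most lists: 0 of the respiratory chain, bile acid, amino acid, hepatocyte identity and MHC class II lists, 1 lower in fatty acid synthesis, 3 lower among male-biased genes, and 1 higher in the extracellular matrix, 3 in lymphocytes and 4 in Kupffer cells, against 20 lower in sterol synthesis and 17 higher in recruited macrophages. With log2(FPKM + 1) fatty acid oxidation (−0.79) lost it, and blood (0.31) and mitochondrially encoded genes (0.82) gained it. With no filter glutathione (−0.20), growth hormone (−0.26), pericentral (−0.24), periportal (−0.31), blood (2.30) and mitochondrially encoded genes (6.26) gained it.

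Settings that leave out several libraries were chosen after seeing the data. Without HFD 1 and 2 fatty acid oxidation (−0.20), P450 (−0.49) and lymphocytes (1.23) lost their call, as they did without HFD 1, 2 and chow 9 (−0.19, −0.46 and 1.22); without HFD 1, 2 and 6 fatty acid oxidation (−0.15) and P450 (−0.52) did. Without HFD 6, 8, 9 and 10 glutathione (−0.48), stress response (−0.39), interferon (0.84), blood (2.77), mitochondrially encoded (7.09) and ribosomal genes (0.42) gained one. The mitochondrial list reversed to −0.45 without HFD 1 and 2, to −0.46 without chow 9 as well and to −0.50 without HFD 6 as well. Counts of called list members moved by over 1.5 times in these settings, given here as higher/lower. The change without HFD 1 and 2 was to 23/0 for acute phase, 23/0 for matrix, 3/0 for interferon, 5/2 for glucose and 4/0 for endothelial genes. It was to 2/0 for cholangiocyte, 1/5 for hepatocyte identity, 2/2 for pericentral, 2/1 for blood, 5/0 for proliferation and 1/6 for mitochondrially encoded genes. Leaving out chow 9 as well gave 23/0 for acute phase, 21/0 for matrix, 3/0 for interferon, 4/0 for endothelial and 2/0 for cholangiocyte genes. It gave 1/4 for hepatocyte identity, 2/2 for pericentral, 2/1 for blood, 4/0 for proliferation and 1/5 for mitochondrially encoded genes. Leaving out HFD 6 in place of chow 9 gave 24/0 for acute phase, 22/0 for matrix, 9/0 for interferon, 16/0 for lymphocytes, 5/0 for endothelial and 2/0 for cholangiocyte genes. It also gave 2/10 for bile acids, 0/17 for amino acids and 3/10 for P450. Hepatocyte identity went to 1/7, pericentral to 5/3, adipocyte to 2/3 and proliferation genes to 8/0. For HFD 6, 8, 9 and 10 left out the counts were 8/1 for acute phase, 14/0 for interferon, 1/2 for clock, 1/1 for stress response and 0/14 for respiratory chain genes. They were 0/0 for cholangiocyte, 0/1 for pericentral and 4/0 for proliferation genes.

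List medians in refits without 1 library, for lists whose call changed, ranged from −0.41 (HFD 7) to −0.25 (HFD 2) for fatty acid oxidation, −0.46 (HFD 6) to −0.15 (HFD 1) for glutathione, 0.38 (HFD 2) to 0.65 (HFD 6) for interferon, 0.69 (HFD 8) to 1.38 (HFD 6) for lymphocytes, −0.34 (HFD 4) to −0.12 (HFD 2) for pericentral, −0.37 (HFD 7) to −0.21 (HFD 1) for periportal, 1.46 (HFD 2) to 2.69 (chow 2) for blood and 4.97 (HFD 2) to 6.49 (HFD 7) for mitochondrially encoded genes.

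Log2 changes of mt-Nd2, mt-Co2, mt-Co3 and mt-Nd4 reversed to −0.32, −0.42, −0.12 and −0.39 with DESeq2, −0.23, −0.75, −0.12 and −0.22 with voom and quality weights, −0.38, −0.33, −0.10 and −0.46 without HFD 1 and 2, −0.37, −0.46, −0.12 and −0.46 without chow 9 as well, and −0.48, −0.63, −0.10 and −0.50 without HFD 6 as well. Those of Hbb-bs, Hba-a1 and Ddx3y (main 1.69, adjusted p = 0.0765) reversed to −0.27, −0.35 and −0.57 with voom and quality weights and to −0.093, −0.12 and −0.59 without HFD 1, 2 and 6.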

Other observations

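The tests of explanations named in the closing section were chosen only after the results were seen, and none is added here. Clock and acute phase transcripts differed between single HFD livers. Arntl was 18.7 CPM in HFD 6, 12.3 in HFD 8, 11.6 in HFD 9 and 8.71 in HFD 10, against 2.78 to 4.89 CPM in HFD 2, 3, 4, 5 and 7 and 0 in HFD 1. Dbp, a clock output gene chosen after its values were seen, was 0.438, 3.84, 8.05 and 2.45 CPM in HFD 6, 8, 9 and 10, where chow ranged from 44.5 to 66.3 CPM. Saa1 was 4079, 3547, 4596 and 17208 CPM in the same 4 livers, 207 in HFD 2 and 61.2 in HFD 1, and 510 to 715 CPM in HFD 3, 4, 5 and 7. The labels give no time of collection.

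HFD 6 and HFD 10 had the lowest Hsd3b5 (0.192 and 0.664 CPM) and Elovl3 (8.66 and 11.4 CPM) and the highest Igfbp1 (2478 and 384 CPM). In HFD 6 Hmox1 was 367, G6pc 958 and Cyp7a1 1.38 CPM. Gpnmb was 14.1 CPM in HFD 6 and 9.93 CPM in HFD 10, the 2 lowest HFD values, and Trem2 was 1.64 CPM in HFD 6. Near Apoe on chromosome 7, Sae1, Igsf23 and Relb, chosen after their values were seen, had log2 changes of 1.40, 3.98 and 1.93 (adjusted p = 0.000172, 5.35e-05 and 0.000172). Sae1 was 17.9 CPM in HFD 6 and 17.3 CPM in HFD 1, against 47.8 to 87.9 CPM in the other HFD libraries and 21.3 to 25.5 CPM in chow. Igsf23 was 1.00 CPM in HFD 6, 0 in HFD 1 and HFD 2, and 9.06 to 21.5 CPM in the other HFD libraries. Relb was 4.33 CPM in HFD 6, 0 in HFD 1, 9.60 CPM in HFD 2 and 3.69 to 4.56 CPM in the others. Apoe was 10124 CPM in HFD 6, 819 CPM in HFD 1 and 220 CPM in HFD 2.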
